A study of Salmo salar with 3 samples.

How the data were processed

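RNA of P. salmonis-infected and of control Atlantic salmon macrophages, both at 24 hours, was measured on 3 two-colour cDNA arrays. Per the labels' protocols, poly(A) RNA was prepared from each condition, about 400 ng went into the first of 2 rounds of linear amplification, and 5 ug of the amplified RNA was labelled by reverse transcription with Cy3 or Cy5. A single yield is given per condition and round (8.1 and 7.8 ug, then 81.2 and 83.3 ug for infected and control), so the arrays were taken as technical repeats of 1 RNA preparation per condition. The labels do not state this outright, and how many fish or cultures went into a preparation is not given in the text available here. Linear amplification before labelling can change the relative level of transcripts, and it acts on both conditions.

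The deposited table holds 1 log ratio per feature and array, treated as log2, with 8736 features, 3 columns and no missing values. The scanner, the background correction, the normalization within arrays, the base of the logarithm and the dye of the numerator are not given in the sources used here, and scanner intensities were not used here. The deposited array medians were 0.11, 0.13 and -0.01, and the deposited values ran from -5.53 to 4.94. Without intensities, no filter on dim features could be applied, and a ratio of a dim feature cannot be told from that of a bright one.

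The choices in this paragraph were made before the data were examined, apart from the following. That the deposited ratios run by dye, and so need turning, was read from the correlations between arrays. That repeat spots are adjacent was read from the layout and the values. The array labels gave each array's dye orientation, and all arrays were turned to infected over control, reading the deposited value as Cy5 over Cy3. Each array was to be centred on its median if any array median lay more than 0.1 from 0, which 2 of the 3 did, so the centred values are the main ones. The mean of the 2 arrays with infected RNA in Cy3 was averaged with the array with infected RNA in Cy5, so that a dye effect of equal size cancels. A feature was counted as changed if it differed by at least 2-fold in the same direction on each of the 3 arrays. This count was set beside the count with the swapped array unturned and beside 100 shuffles of the features of the other arrays against those of slide 3. No test of infection was made, since each condition was taken to have 1 preparation. The naming rule took the 15 largest changed features in each direction, then up to 4 members of each list with at least 3 measured genes and the same sign on all arrays, and at most 2 unnamed features per direction. Repeat spots are named once, so each unnamed feature is the larger of an adjacent pair.

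Feature names came from the platform annotation supplied with the table, which dates from before current symbols. It named 192 features (2.2%) by 44 symbols, in 45 gene entries, each with 1 symbol, and the other 8544 features are unnamed here. Through the gene number, 42 of the 45 entries matched the Ssal_v3.1 RefSeq gene table, which gave current symbols and aliases, and 3 (mt-a, rps7 and 1 sod1 entry) did not. Among the 42 matched entries, 8 have a locus number and no other name. A gene's value is the mean of its features. The word clone stands for 1 expressed sequence tag of the annotation. Lists were matched on symbols and aliases, since no gene descriptions were given. The aliases C209E, CLC4E, FRIH, FRIM and EF1A2 were assigned to lists by hand after the annotation was seen. The prefix for mitochondrial genes was kept from taking mt-a, which is a metallothionein. Counted by gene entries, 4 of the 26 lists had at least 3 genes, 10 had 1 or 2, and 12 had none. Random lists were drawn 10000 times from the 45 named entries and, as a choice made after the data were seen, from all spot pairs. No intensities were given, so the draws were not matched on level.

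Feature numbers were read as 12 by 4 subgrids of 13 rows and 14 columns. All 96 named spot pairs of 1 clone sat in adjacent odd and even columns. Over the array such neighbours correlated at r = 0.97, against 0.06 for even columns and the next odd one, so most features appear to be spotted in adjacent pairs. Spots were kept apart in the main count, as each has its own number. The median absolute difference of adjacent spots was 0.06 on the log2 scale.

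The alternatives were other fold thresholds, the dye-balanced mean in place of each array, each array left out, the values as deposited, scaling by the median absolute deviation, quantile normalization, unweighted means, single dye orientations, Spearman's rho, and a limma test over the 3 arrays with and without a dye term. Averaging adjacent spots, reading the values as natural or base 10 logarithms, the agreement of arrays without the changed features and the list percentiles under the other dye reading were added after the data were seen. A filter on low intensity could not be run. No feature number repeated and no value was missing, so the settings for repeated numbers and missing values changed nothing.

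The fold rule was tested on simulated data, with residuals of the 3 arrays as noise on 8736 features for the infected over control comparison. Of 50 features each simulated at 3-fold, 4-fold and 8-fold, 100% were found. At exactly 2-fold, 4% were found, since every array must pass. None of the unchanged features was called. Of 200 features with a dye effect alone, 0 were called, which the rule fixes in advance, since that effect has opposite turned signs in the 2 orientations. The residuals were taken around the mean of the same arrays, from weakly changed features, and drawn for each array apart. The simulated noise may therefore be smaller than that of the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 were used, and figures were drawn with matplotlib 3.10.9.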

Results

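Atlantic salmon (Salmo salar) macrophages that had been infected with Piscirickettsia salmonis, an intracellular bacterium that causes disease in farmed salmonids, were compared with non-infected macrophages after 24 hours. The comparison asks which transcripts differ between the infected and the control cells. Messenger RNA of the 2 conditions was amplified in 2 rounds, labelled with Cy3 and Cy5 and hybridised together to 3 cDNA arrays of 8736 features each. The infected RNA carried Cy3 on 2 arrays (slides 3 and 4) and Cy5 on the third (slide 5). A value given below without slide 5 therefore rests on 1 dye orientation, and a dye effect does not cancel in it. The labels give a single amplification yield per condition, so the 3 arrays were taken as repeat hybridisations of 1 infected and 1 control preparation. The labels do not state this outright, and the number of fish or cultures behind each preparation is not given in the text available here. An SD below therefore measures hybridisation and dye error over 3 arrays. It does not measure the spread between cultures or fish, no p-value for infection was computed, and the number of arrays limits the precision.

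The deposited values are log ratios of the 2 channels. Their base is not stated in the sources used here and is read as 2, so each fold below holds for that base. Slides 3 and 4 correlated with Pearson's r = 0.89 across features, while slide 5 correlated with them at r = -0.76 in both cases. The columns therefore run by dye, and the swapped array was turned against the others. Which dye is the numerator is not stated either. Values are given as infected over control under the usual Cy5 over Cy3 reading, so that a positive value means a higher level in infected macrophages under that reading. If the deposited ratio was Cy3 over Cy5, every sign and every side named below turns, and the percentiles of lists turn to the values given beside them for that other dye reading.

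On every array, 227 of the 8736 features differed by at least 2-fold in the same direction. Of these, 179 lay on the positive side and 48 on the negative side. This excess held at 1.5-fold (311 and 164), at 3-fold (88 and 19) and with the values read as natural logarithms (262 and 106). It was nearly lost with base 10, where the sides would be 528 and 471, and it was absent without a fold rule. A limma test over the arrays, which measures hybridisation spread alone, gave 638 positive and 669 negative features, or 898 and 1099 with a dye term. Averaging adjacent spots kept the excess of the fold rule, with 91 positive and 25 negative of 4368 spot pairs. The median size was 3.32-fold on the positive side and 3.02-fold on the negative side. The dye-balanced log2 ratios of these features ran from 1.03 to 5.13 and from -4.32 to -1.11, and their median SD over the arrays was 0.14. No feature met the same rule when the swapped array was left unturned, which is the direction of a dye effect. The need for turning was itself read from the correlations of these arrays, so this count is not independent of it. Shuffling the features of the arrays against each other gave 0.14 such features on average and at most 1 in 100 shuffles. The sign was shared by all 3 arrays for 47.7% of features, against 27.96% in the dye direction. A feature with the same sign on slides 3 and 4 falls in just 1 of these shares, so they are not independent of each other. The 25% that 3 independent arrays would give is too low a base for either share. Slides 3 and 4 have the same dye orientation and correlated at r = 0.89. Most features changed little, and the median absolute log2 ratio was 0.13, close to the median SD over arrays of 0.15.

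**Figure D1:**
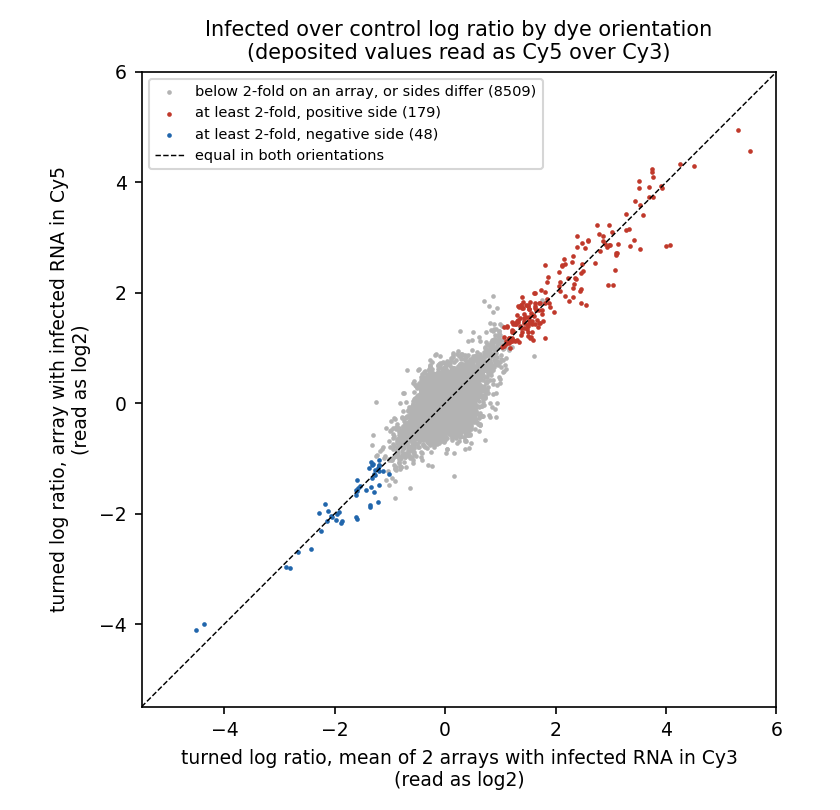
Each point is 1 of 8736 features, with the turned log ratio (read as log2) averaged over the 2 arrays with infected RNA in Cy3 on the x axis and on the array with infected RNA in Cy5 on the y axis. The 179 features at least 2-fold on the positive side of every array (red) and the 48 on the negative side (blue) lie along the dashed line of equal ratios.

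The strongest values among features with a gene name belonged to C-type lectins, receptors that bind sugars on microbes and cells. LOC100136446, for which the reference lists the alias C209E (a CD209 antigen-like lectin), had a log2 ratio of 3.34 ± 0.08 (SD over 3 arrays), or 10.1-fold, and its 3 clones lay between 2.83 and 3.74. It was the single named gene among the 15 largest positive values. LOC100136447, with the alias CLC4E (C-type lectin domain family 4 member E, a pattern recognition receptor of mammalian macrophages), had a log2 ratio of 3.20 ± 0.44 (SD over 3 arrays), or 9.16-fold, with clones at 2.95 and 3.45. All 6 features of the first gene and all 4 of the second were at least 2-fold positive on every array. These are the measured members of the list of pattern recognition receptors, and they were assigned to it by alias after the annotation was seen. CLC4E falls outside the naming rule and was named after its values were seen.

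Antigen presentation genes lay on the positive side together. All 5 measured genes of this list were positive on all 3 arrays, and none reached 2-fold as a gene on every array. b2m, the light chain of MHC class I, had a log2 ratio of 0.75 ± 0.04 (SD over 3 arrays), or 1.68-fold, over 24 features of 11 clones. psmb8b, an immunoproteasome subunit, was at 0.57 ± 0.03, or 1.49-fold. tapbp (tapasin, which loads peptides onto MHC class I) was at 0.43 ± 0.07, and tap1, a subunit of the peptide transporter, at 0.43 ± 0.16. The fifth member, psmb9b, another immunoproteasome subunit, was at 0.31 ± 0.16, or 0.18 without slide 5, and was chosen after its value was seen. In the Ssal_v3.1 reference, psmb8b and psmb9a (the current name of psmb9b) lie on the same chromosome with 2 genes between them. The list's median of 0.43 ± 0.12 (SD over 3 arrays) stood at percentile 97.7 of 10000 random lists of 5 named genes and at 99.85 of lists of spot pairs from the whole array (3.44 and 0.16 under the other dye reading), a description of these arrays and not a test of infection. Counting each feature instead of each gene gave a median of 0.74, since most features of the list are b2m clones. Of the 11 b2m clones, 9 lay between 0.70 and 1.12, while the other two lay at 0.03 and -0.11. The haemoglobin genes, markers of erythrocytes, were positive on every array as well, at a median of 0.36 ± 0.19 (SD over 3 arrays).

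The 3 measured iron handling genes gave values of very different size. Transferrin (trf, current symbol tfa), the plasma protein that carries iron, had a log2 ratio of 2.005 ± 0.14 (SD over 3 arrays), or 4.01-fold, over 14 features. Its 7 clones were all positive on every array but ranged from 0.55 to 3.13, and 8 of its 14 features were at least 2-fold on every array. LOC100136565, with the alias FRIM (ferritin middle subunit, an iron store), was at 0.45 ± 0.14, and its 3 clones lay between 0.39 and 0.54. LOC100136564, with the alias FRIH (ferritin heavy subunit), was at 0.03 ± 0.17 (0.17 without slide 5), a value smaller than its SD, and its arrays differed in sign. The median of the 3 genes was 0.45 ± 0.14, which is the value of FRIM alone. It stood at percentile 96.9 of random lists of named genes and 98.8 of lists of spot pairs (4.36 and 1.17 under the other dye reading). The percentile therefore describes the middle gene and not a shift shared by the list. The ferritins entered this list by alias after the annotation was seen. Transferrin is also the measured member of the list of acute-phase, antimicrobial and complement genes.

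The antioxidant and redox list went both ways. Its 2 metallothionein entries, which bind zinc and copper, were negative on every array. mt-a was at -0.62 ± 0.02 (SD over 3 arrays), a 1.54-fold difference, and LOC100136589 (alias mta) at -0.40 ± 0.14, with clones at -0.70 and -0.11. The 2 entries of sod1, the cytosolic superoxide dismutase, were positive on every array, at 0.24 ± 0.30 and 0.22 ± 0.11. The larger of these was smaller than its SD, and it was 0.095 without slide 3 and 0.38 without slide 4. The list's median of -0.09 ± 0.08 stood at percentile 6.5 of random lists of named genes and 17.7 of lists of spot pairs (93.5 and 82.3 under the other dye reading). The list reaches the minimum of 3 genes by entries alone, since sod1 and metallothionein A each stand in it under 2 entries. Its median lies between these opposed pairs, so the percentile says little. Its mean of -0.14 had the same sign, and its median was -0.15 without slide 3 and also without slide 5.

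**Figure D2:**
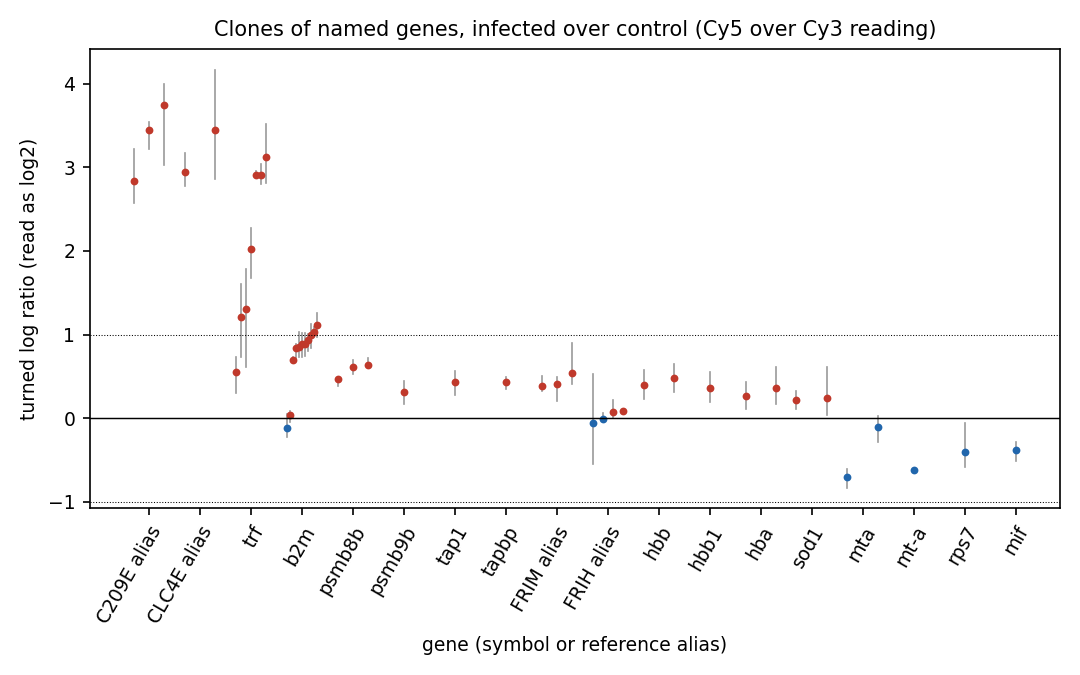
Each point is the dye-balanced log ratio (y axis, read as log2) of 1 clone of a named gene (x axis), in red above 0 and blue below, and the grey line spans its lowest and highest array. The C-type lectin and transferrin clones reach furthest from 0, 9 of 11 b2m clones sit between 0.70 and 1.12, and the metallothionein, rps7 and mif clones lie below 0. Dotted lines mark a 2-fold difference.

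Haemoglobin genes were the measured members of the erythrocyte list. LOC100136576 (alias hbb) was at 0.44 ± 0.19 (SD over 3 arrays), LOC100136584 (alias hbb1) at 0.36 ± 0.19 and hba at 0.31 ± 0.20 (0.48 without slide 5), and all 10 features were positive on every array. The list's median stood at percentile 90.4 of random lists of named genes and 98.6 of lists of spot pairs (11.95 and 1.39 under the other dye reading). Its members are all haemoglobin genes and may move together, while the random lists drew genes of any kind. The percentiles are therefore a description alone. Both arrays with infected RNA in Cy3 gave medians of 0.56 and 0.51, and the swapped array gave 0.20. The single measured gene of the stroma, epithelium and liver list, LOC100136573 (alias apoa1, an apolipoprotein), was at 0.03 ± 0.06 (-0.02 without slide 5).

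The other lists fixed beforehand had at most 2 measured genes. The naming rule does not cover their members, which are given here to complete the lists. On the positive side on every array were hsp90b, a cytosolic chaperone, at 0.32 ± 0.12 (SD over 3 arrays; 0.21 without slide 5) and antithrombin, a serine protease inhibitor, at 0.19 ± 0.08. psmb8b and psmb9b were the measured genes of the proteasome and ubiquitin list, whose median was 0.44 ± 0.08. On the negative side on every array were rps7, a ribosomal protein, at -0.40 ± 0.27 (-0.22 without slide 5) and LOC100136525 (alias EF1A2, a translation elongation factor) at -0.16 ± 0.06. The nuclear transport GTPase ran1 was at 0.01 ± 0.11 (0.10 without slide 5) and the apoptosis regulator mcl-1 at -0.07 ± 0.26 (-0.29 without slide 5), both with arrays that differed in sign. The remaining 12 of the 26 lists matched no named gene by their fixed symbols and were not analysed here. Among them were inflammatory cytokines, interferon response genes, NADPH oxidase and macrophage markers. The words fixed for the lists were not matched, since no gene descriptions were given. By the word macrophage, the measured mif (macrophage migration inhibitory factor) would enter the macrophage markers, but it was not assigned to them. The cytokine list as fixed leaves out mif as well.

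Most of the changed features have no gene name here. The annotation named 192 of the 8736 features, and 18 of the 227 changed features, all on the positive side, belonging to 3 genes. The 161 other positive and all 48 negative features are known by position alone. Adjacent spots are named once here, by the larger value. Among the 15 largest positive values 13 were unnamed, led by feature 1040112 at 5.13 ± 0.26 (SD over 3 arrays), or 34.9-fold, whose neighbour lay at 5.05, and then feature 11010408 at 4.40 ± 0.60. All 15 largest negative values were unnamed, led by feature 7011303 at -4.32 ± 0.26, a 19.9-fold difference, whose neighbour lay at -4.19, and then feature 9030604 at -2.92 ± 0.05.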

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

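Leaving out each array in turn gave 241 to 248 features changed at least 2-fold, against 227 with all 3. Such a count cannot fall below 227, since the rule asks every array used to pass. The values as deposited gave 220 features, 165 of them positive. The count moved with the rule itself: 475 features at 1.5-fold (311 positive and 164 negative) and 107 at 3-fold (88 and 19). Averaging adjacent spots gave 116 of 4368 spot pairs, a share of 2.66% against 2.60% of features. Read as natural logarithms the count was 368 (262 positive and 106 negative), and read as base 10 logarithms 999 (528 and 471). A limma test over the 3 arrays at an adjusted p of 0.05, which measures hybridisation spread alone, gave 1307 features without and 1997 with a dye term. The sides were 638 positive and 669 negative without the dye term, and 898 and 1099 with it. The median absolute log2 ratio of 0.13 ranged from 0.14 to 0.17 with an array left out, and was 0.17 on the arrays with infected RNA in Cy3 and 0.19 on the swapped array. Spearman's rho between arrays was 0.72, 0.36 and 0.38 where Pearson's r was 0.89, 0.76 and 0.76. Without the 227 changed features, a setting added after the data were seen, Pearson's r was 0.76, 0.46 and 0.47. Counting each feature moved the antigen presentation median from 0.43 to 0.74, and no other setting moved a list median by more than its SD over arrays. All 28 named genes with the same sign on all 3 arrays kept it in the mean with the values as deposited and with quantile normalization. Scaling, the unweighted mean and leaving out an array could not change it, because the arrays already shared the sign.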

Other observations

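All tests in this part were chosen after the results were seen. Muscle and pituitary genes were chosen after their values were seen, and the muscle genes lay near 0 with all 3 arrays. The 3 muscle genes (LOC100137051, alias Parvb1, and prvb, both parvalbumins, and mlc-2, a myosin light chain) had a median log2 ratio of 0.03 over the 3 genes (-0.02 without slide 5, when the genes lay at 0.15, -0.12 and -0.02), and single features ran from -0.19 to 0.32. The 2 pituitary genes (LOC100136588, alias gh, growth hormone, and pit-1, its transcription factor) lay at 0.07 and 0.15 (0.25 and 0.28 without slide 5). None of these 24 muscle and 8 pituitary features was changed by the fold rule. The haemoglobin genes, also of another cell type, lay at 0.31 to 0.44. LOC100136498 (alias mif, macrophage migration inhibitory factor) was negative on every array at -0.38 ± 0.11 (SD over 3 arrays), and LOC100136385 (alias CIRBP, a cold-inducible RNA-binding protein) positive at 0.31 ± 0.19. fadsd6, a fatty acid desaturase, lay at -0.22 ± 0.08 and hn1 at -0.20 ± 0.19 (-0.36 without slide 5), both negative on every array. The 8 entries with a locus number alone lay between -0.06 and 0.21.

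Strong changes lay mostly on the side of the C-type lectins, 179 features against 48 with the values read as log2. Read as natural logarithms the sides were 262 and 106, and as base 10 logarithms 528 and 471. The centring applied here is argued against as the cause. The positive share was 75% with the values as deposited and between 68.9% and 74.1% there with an array left out. A shift of 0.36 would be needed to even the sides. The normalization before deposit is not known, and its effect was not tested. Repeat clones of a few genes may contribute, since the 18 changed named features came from 3 genes with 6, 4 and 8 features, a mean of 6, but with no named feature on the negative side this stays open. A difference between the preparations unrelated to infection cannot be told apart from infection, as the labels point to 1 RNA preparation per condition. Among the limma calls over arrays the sides were 638 positive and 669 negative, or 898 and 1099 with a dye term.

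Clones of a single gene gave different values. The 7 transferrin clones differed by 2.57 on the log2 scale, and 2 of 11 b2m clones lay near 0 while the other 9 averaged 0.91. Noise between spots is argued against for transferrin, where the SD between clones was 11.4 times the SD between spots of a clone. This ratio was 13.7 with infected RNA in Cy3 and 4.82 in Cy5. A dye effect on some clones would spread them in both orientations, so these ratios cannot decide on it. Alone, it would reverse the order of the clones between orientations. Clones with means of 2.02 or more lay at 1.68, 1.87 and 2.27 or more on slides 3, 4 and 5. The other clones lay at most at 0.87, 1.03 and 1.79. A dye effect as the whole cause is therefore argued against. Clones of different or related transcripts under the same symbol remain a candidate explanation for the range of 2.57, which stays open because no clone sequence was matched here.

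Haemoglobin and antigen presentation genes were positive together. The centring applied here is argued against for haemoglobin, whose features had a median of 0.30 as deposited, with all 10 positive on every array. An effect of normalization before deposit was not tested. Erythrocytes would bring far more haemoglobin RNA than b2m RNA, and b2m lay 0.31 above the highest haemoglobin gene (SD of the difference over 3 arrays, 0.24). By this measure erythrocyte RNA is argued against as the source of the b2m value, but weakly. Scanner intensities were not used, so a compressed ratio at bright haemoglobin spots could not be checked. The gap was 0.11, 0.10 and 0.51 on slides 3, 4 and 5, so its SD mostly reflects the difference between the dye orientations. Without slide 5 the gap was 0.11, less than that SD, but a dye effect does not cancel in this value. For psmb8b, psmb9b, tap1 and tapbp it stays open. The lowest, psmb9b, lay at -0.13 relative to the highest haemoglobin gene, within the SD of 0.35. Both tapbp and tap1 lay at 0.43, against 0.44 for that haemoglobin gene. The value of psmb8b was higher, at 0.57. On slides 3, 4 and 5 psmb8b lay at 0.60, 0.54 and 0.57, and that haemoglobin gene at 0.60, 0.61 and 0.27. An effect of infection on the haemoglobin and antigen presentation genes was not tested, for lack of a second preparation.

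Differences between subgrids carried little of the infected over control signal. Position within a subgrid was not tested, and the normalization before deposit is not known. The 48 subgrids held 1.46% of its variance across features and 5.87% of the variance in the dye direction.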
